A study of Homo sapiens with 23 samples.

How the data were processed

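RNA from xenograft tumours of C4-2B, an established human prostate cancer cell line, was sequenced by the authors. Per the labels, cells in matrigel were placed under the skin of nude mice, treatment began when tumours were visible, and tumours were taken at no more than 1000 mm3 or when 21 days of daily dosing had passed. The tumours were dissociated with collagenase IV, RNA was purified on RNeasy MinElute columns, and libraries were made with the KAPA RNA HyperPrep kit. Whether RNA was selected for poly(A) tails or depleted of ribosomal RNA is not given in the sources used here.

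The labels name 23 samples in 7 groups. The 22 with a file were used: 3 vehicle, 2 untreated, 3 mycophenolate mofetil (MMF), 4 abiraterone, 3 ARN-509, 3 MMF with ARN-509, and 4 MMF with abiraterone and prednisolone phosphate, called the triple combination here. The sample MMF A was not analysed here. Vehicle was 0.1 ml of 5% benzyl alcohol in 95% safflower oil, given into the peritoneum, which is also the carrier of abiraterone. MMF (100 mg/kg) in saline and ARN-509 (30 mg/kg) in another carrier were given by mouth, so their route and carrier differ from those of the vehicle group. Abiraterone was given at 0.5 mmol/kg/day and prednisolone phosphate at 20 mg/kg. The label of the abiraterone group breaks off after the words "together with", so whether this group also received another agent is not given in the sources used here. The labels do not say whether the libraries of a group come from separate animals, so every p-value of a gene here measures the spread between samples.

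The authors deposited raw read counts per gene name, one file per sample, with closing lines for reads assigned to no gene, ambiguous reads and reads aligned at several places. The submitters' processing notes name bcl2fastq 2.19, STAR 2.4.2a, HTSeq and DESeq2 (versions not given), and the builds GRCh37, hg19 and mm8, with no role or order. The annotation, the strand setting and the handling of reads from mouse host cells are not given in the sources used here. No coordinates are printed, since the reference at hand is of another build. Each file held the same 55765 gene names. Total gene counts ran from 9376335 to 17130511 per library, so 1 CPM (counts-per-million) stands for 9.38 to 17.1 reads before scaling. Levels are printed after the scaling given below. There 3 reads stood for 0.104 CPM in MMF+ARN-509 A and 0.613 CPM in triple combination D, so levels under 1 CPM can rest on few reads. A count of 0 allows up to 3 reads, and this limit covers counting error only.

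Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16589. Libraries were scaled by trimmed mean of M values (TMM), and one quasi-likelihood model with a mean for each of the 7 groups was fitted to all 22 libraries (15 residual degrees of freedom, common biological coefficient of variation 0.511). There were 12 comparisons, 2 of them interactions, each tested on both sides by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. By chance 829 genes are expected at an unadjusted p under 0.05. Levels are CPM with TMM scaling, as mean ± SD over the libraries of a group, and SE is the standard error of a log2 fold change.

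The comparisons, tests, 31 gene lists, named-gene rule and most alternatives were fixed before the data were examined. The rule always names IMPDH1, IMPDH2, CYP17A1, KLK3, KLK2, TMPRSS2 and FKBP5. It adds the 10 genes with the largest rise and the 10 with the largest fall past the threshold without overlap between groups, up to 4 members of each list with a call, and, where fewer than 5 genes pass, the 5 genes with the smallest p, stated as not past the threshold. Pseudogenes and clone-named genes may stay unnamed. Where no member of a list passed the threshold over all genes, the members given as examples were chosen by smallest p after their values were seen. Some genes and lists that were tested are not reported here, and the counts of genes and list tests include them.

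Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), which asks whether a list's members lie higher or lower than other genes. Its inter-gene correlation was preset at 0.01, and adjustment ran over all 372 tests of a list in a comparison. The p-value at this preset compares genes within the same libraries and rests on the assumed correlation. It does not by itself measure the spread between samples. Beside each call stands the adjusted p of the same test with a correlation estimated from the data, and fry, a rotation test of the list by itself, was run as well. With the preset value 94 of the 372 tests passed. With an estimated correlation 0 passed (smallest adjusted p = 0.276), and with fry 0 passed (smallest adjusted p = 0.0967, and 0.722 for change in either direction). Members were also counted after adjustment over the list alone.

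The procedure was tested on simulated data with counts drawn at these means and spreads. Of 50 genes changed 4-fold, edgeR found 52% for MMF against vehicle, 68% for abiraterone against vehicle, 80% for the triple combination against abiraterone and 28% for untreated against vehicle. At 8-fold these shares were 90%, 94%, 100% and 76%, and at 2-fold 2%, 4%, 8% and 2%. False calls numbered 4 to 7 with edgeR, 3 to 5 with limma voom, and 36 to 40 with DESeq2 1.42.0. Genes were drawn independently and the changed ones above a minimum level, so variation shared by the genes of a library was not simulated. The rates may thus differ on real libraries. Other splits of the real libraries gave edgeR up to 1357 genes past the threshold for MMF and 3526 for MMF with ARN-509 against vehicle. Beside ARN-509 and abiraterone the interactions gave up to 3785 and 4698. The triple combination against MMF gave up to 46, the other comparisons split 0. Untreated against vehicle was not split.

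Alternatives were DESeq2, edgeR with DESeq2 size factors, no low-count filter, only the groups compared, the letter in the sample names as a block, voom with sample quality weights, untreated and vehicle libraries together as control, and leaving out each library in turn. Chosen after seeing the data were a covariate for the share of reads on no gene, the omission of the 4 libraries with over 25% of uniquely aligned reads on no gene (Vehicle B, Vehicle C, MMF C and MMF+ARN-509 A, which leaves 1 vehicle library), and the same changes, size factors and omission of each library for the lists. Correlations across libraries have permutation p-values on both sides.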

Results

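Gene expression was measured by RNA sequencing in tumours grown from C4-2B cells, a castration-resistant human prostate cancer line. The series asks how targeting androgen synthesis and action affects such tumours, alone and with a block of nucleotide synthesis. MMF releases mycophenolic acid, an inhibitor of inosine monophosphate dehydrogenase (IMPDH), which makes guanine nucleotides. Abiraterone inhibits CYP17A1, an enzyme of androgen synthesis, and ARN-509 (apalutamide) is an antiandrogen. Total gene counts per library averaged 13253900 ± 1699060 in vehicle (SD, n = 3), 11246100 ± 547489 in untreated (n = 2), 12387000 ± 3248380 in MMF (n = 3), 14457800 ± 2294920 in abiraterone (n = 4), 14163000 ± 1702670 in ARN-509 (n = 3), 14122300 ± 151630 in MMF with ARN-509 (n = 3) and 13432400 ± 1306240 in the triple combination (n = 4). The lowest total was 9376335 (MMF D) and the highest 17130511 (Abiraterone C). These group sizes hold below except where libraries are said to be left out or controls pooled. Members given as examples of a list, beyond the genes always named, were chosen by smallest p after their values were seen. A list that rose or fell is one whose test passed, with members counted by direction, so single members need not have changed.

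Libraries differed within groups in their make-up. Mitochondrial genes, which encode respiratory chain subunits, took from 20.7% of gene counts in MMF+ARN-509 A to 80.9% in triple combination D. Their share averaged 37.2 ± 17.5% in vehicle, 50.2 ± 33.3% in untreated, 54.9 ± 3.27% in MMF, 45.7 ± 9.59% in abiraterone, 54.7 ± 10.6% in ARN-509, 49.2 ± 26.9% in MMF with ARN-509 and 68.6 ± 8.75% in the triple combination. Uniquely aligned reads that fell on no gene made up 7.09% to 43.3%. This share averaged 26.2 ± 13.9% in vehicle and 11.2 ± 3.49% in the triple combination. Over the 22 libraries it went with a lower mitochondrial share (Pearson r -0.846, Spearman rho -0.889, permutation p = 1e-05 for each, the smallest these permutations can give). Without the 2 libraries farthest from the median r was -0.768, and for deviations from group means it was -0.837. It also went with the first principal component of expression (r 0.814, rho 0.788, permutation p = 1e-05 and 8e-05, r 0.802 without 2 libraries, 0.871 within groups) and with the number of genes that had a count (r 0.894, rho 0.924, permutation p = 1e-05 for each, r 0.896 without 2 libraries). Adjusted over these 3 relations, p was 1e-05 for each r and at most 8e-05 for rho. Mitochondrial reads lie in the total of which the share of reads on no gene is taken. Part of its relation to the mitochondrial share is therefore built in, also where it serves below as covariate for mitochondrial genes. Libraries over 25% were Vehicle B and C, MMF C and MMF+ARN-509 A. Without these 4, MMF and MMF with ARN-509 keep 2 libraries each, and vehicle keeps Vehicle A alone. For single comparisons that omission is therefore used below only where vehicle is not involved. Totals over all comparisons that include it say so.

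**Figure D1:**
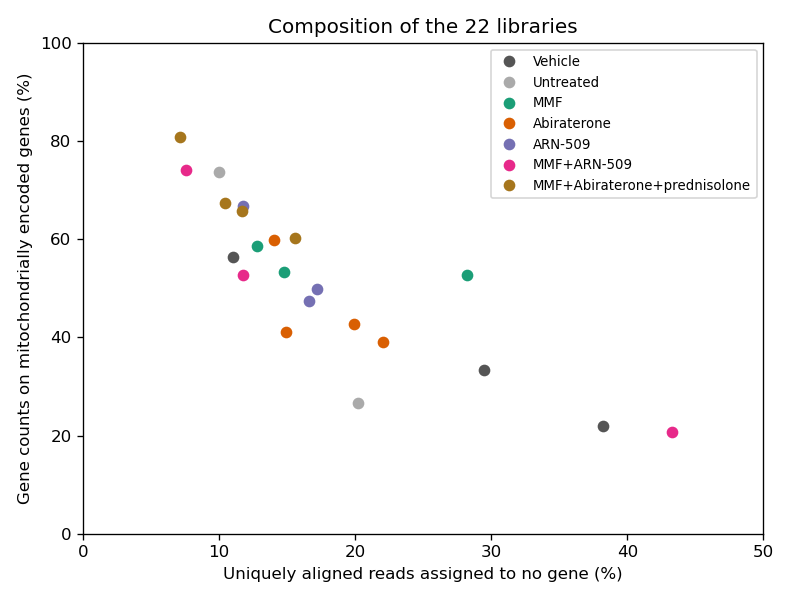
Share of gene counts on mitochondrial genes (%, vertical) against share of uniquely aligned reads on no gene (%, horizontal), one point per library (22), coloured by group. Libraries run from 7.09% to 43.3% across and from 80.9% down to 20.7%, and the 3 vehicle libraries lie far apart.

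Genes the drugs act on, and a prostate gene of the fixed set, are given first. IMPDH1 stood at 56.1 ± 17.6 CPM in vehicle, 68.3 ± 11.7 in MMF and 69.5 ± 19.4 in the triple combination. IMPDH2, the isoform that is usually more abundant in dividing cells, stood at 71.6 ± 13.3, 80.8 ± 15.9 and 133 ± 60.9 CPM. TMPRSS2, a serine protease of the prostate, was at 305 ± 157 CPM in vehicle, 389 ± 134 in abiraterone, 406 ± 131 in ARN-509 and 348 ± 54.9 in the triple combination. CYP17A1 had 1 read each in Vehicle C, MMF C and Abiraterone A and 0 in every other library, where a count of 0 allows up to 3 reads (0.104 to 0.613 CPM). It was not detectable at this depth in most libraries and was not tested.

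MMF was compared with vehicle to see what IMPDH inhibition alone changes. KLK3, which encodes prostate-specific antigen, was at 625 ± 442 CPM against 312 ± 59.0 (log2 fold change 1.00, SE 0.66), but 0.48 without MMF D. The co-chaperone FKBP5 was at 141 ± 25.04 against 79.2 ± 5.00, and neither gene passed the threshold (adjusted p = 0.952). Cholesterol synthesis and uptake rose as a list, with 21 of 24 members higher (adjusted p = 0.000275, and adjusted p = 0.849 with an estimated correlation). Its members include squalene epoxidase SQLE (9.46 ± 1.42 against 6.25 ± 0.767 CPM) and INSIG1, a sterol sensor of the endoplasmic reticulum (105 ± 43.5 against 49.1 ± 36.0). The unfolded protein response rose as a list, with 19 of 24 members higher (adjusted p = 0.00218, and adjusted p = 0.849 with an estimated correlation). Among them were MANF, a secreted protein of stressed endoplasmic reticulum (12.9 ± 2.52 against 6.29 ± 1.65), and CRELD2 (41.1 ± 19.9 against 22.4 ± 2.20). Proliferation lists fell: G2/M and mitosis with 37 of 42 lower (adjusted p = 0.00476) and S phase and DNA replication with 35 of 42 lower (adjusted p = 0.0189), each with adjusted p = 0.988 with an estimated correlation. CDC25C, the phosphatase that starts mitosis, was at 2.43 ± 1.74 against 4.63 ± 2.47 CPM. Hypoxia genes fell as a list, with 25 of 35 members lower (adjusted p = 0.034, and adjusted p = 0.978 with an estimated correlation), among them the angiogenic factor VEGFA (73.7 ± 16.6 against 176 ± 69.3). Transcripts of the erythrocyte list fell, with 4 of 4 measured members lower (adjusted p = 6.32e-11, and adjusted p = 0.276 with an estimated correlation), with 4 past 0.05 adjusted over the list alone. The haemoglobin chain gene HBB was at 3.68 ± 4.52 against 314 ± 289 CPM. Its reads can be shared with paralogs such as HBD, so the level of either is uncertain. The tumours grew in mice, so reads on such markers can be mouse reads counted on human genes, or human transcripts of the tumour cells. These were not told apart, here or for the endothelium, fibroblast, EMT, muscle and myeloid lists. ALAS2, which starts haem synthesis in red cells, was at 0.526 ± 0.772 against 38.3 ± 39.5. Mitochondrially encoded genes rose as a list, with 13 of 13 members higher (adjusted p = 1.92e-06, and adjusted p = 0.864 with an estimated correlation). Ribosomal proteins rose as a list, with 40 of 40 members higher (adjusted p = 2.39e-06, and adjusted p = 0.902 with an estimated correlation), and endothelium fell as a list, with 7 of 11 members lower (adjusted p = 0.0441, and adjusted p = 0.883 with an estimated correlation). De novo purine synthesis, the pathway of IMPDH, did not pass (adjusted p = 0.656). Untreated tumours showed the same erythrocyte, G2/M, S phase, mitochondrial and ribosomal directions against vehicle (below).

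By gene, edgeR called 0 of 16589 for MMF, with 309 at an unadjusted p under 0.05, while DESeq2 called 2 and voom 0. The smallest p-values, not past the threshold (adjusted p = 0.952), belonged to ALAS2, HBD and the chromatin protein gene JARID2, besides a pseudogene and a clone-named gene. JARID2 stood at 441 ± 723 CPM against 22.1 ± 6.46, since MMF D alone had 1276. Leaving out one library ended the calls for cholesterol (MMF C, adjusted p = 0.093), the unfolded protein response (Vehicle A, 0.052), G2/M (Vehicle B or MMF D, up to 0.919), S phase (Vehicle A or B, MMF B or D, up to 0.946), hypoxia (Vehicle A or C, MMF B or C, up to 0.931) and endothelium (Vehicle A or B, MMF C, up to 0.422). The mean log2 fold change of mitochondrial genes went from 1.22 to 0.66 with the no-gene share as covariate, and that of ribosomal proteins from 0.54 to 0.13, or to 0.22 with the letter as a block. In each of these alternatives the call stayed, with a smaller effect. With the covariate endothelium had adjusted p = 0.0602.

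Abiraterone was compared with vehicle for the effect of blocking androgen synthesis. KLK3 was at 66.4 ± 20.2 CPM against 312 ± 59.0 (log2 fold change -2.23, SE 0.62, adjusted p = 0.541), lower in 4 of 4 libraries than in any vehicle library. KLK2, a related prostate kallikrein, was at 55.0 ± 6.35 against 115 ± 33.3 (-1.06, SE 0.40, but -0.69 with untreated and vehicle together as control), and FKBP5 at 111 ± 42.7 against 79.2 ± 5.00. Fibroblast and matrix genes rose as a list, with 19 of 22 members higher, median 1.09 (adjusted p = 4.13e-05, and adjusted p = 0.883 with an estimated correlation), among them the collagen COL3A1 (41.8 ± 27.4 against 14.2 ± 16.6) and smooth muscle actin ACTA2 (23.7 ± 18.7 against 7.58 ± 4.46). EMT and mesenchymal genes rose as a list, with 13 of 15 members higher (adjusted p = 0.000958, and adjusted p = 0.849 with an estimated correlation). This list shares FBN1, MMP2, SPARC and TAGLN with the fibroblast list, so calls of the EMT and fibroblast lists are not independent, here and below. Vimentin VIM was at 69.7 ± 50.9 against 31.4 ± 14.4. Immediate early and heat shock genes, which respond to handling, rose as a list, with 23 of 29 members higher (adjusted p = 0.00307, and adjusted p = 0.849 with an estimated correlation). The transcription factor JUN was at 69.7 ± 11 against 37.6 ± 2.01. Cholesterol synthesis and uptake rose as a list, with 21 of 24 members higher (adjusted p = 0.00375, and adjusted p = 0.849 with an estimated correlation). Mevalonate decarboxylase MVD was at 13.6 ± 3.33 against 7.57 ± 1.91. Histones rose as a list, with 14 of 17 members higher (adjusted p = 0.0277, and adjusted p = 0.933 with an estimated correlation) and mitochondrial genes with 12 of 13 higher (adjusted p = 0.0343, and adjusted p = 0.978 with an estimated correlation).

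For abiraterone edgeR called 0 genes, with 837 at an unadjusted p under 0.05 (285 higher, 552 lower), while DESeq2 called 24 and voom 104. The 5 smallest p-values, at adjusted p = 0.46 and so not past the threshold, were those of TNS4, VWDE, POTEH, ORM1 and NES, all lower. NES, an intermediate filament of progenitor cells, was at 0.237 ± 0.214 CPM against 8.45 ± 11.4, with 21.6 in Vehicle B. ORM1, a plasma glycoprotein, had no read in abiraterone, which allows up to 0.127 to 0.238 CPM per library, against 0.892 ± 0.683. POTEH has close paralogs, so its 0.129 ± 0.146 against 10.6 ± 11.6 CPM is uncertain. KLK3 passed in 2 of 16 alternatives (adjusted p from 0.000284 to 1). These were voom and the fit without a low-count filter. The latter gave the lowest value and also called 15 to 36 genes in simulated unchanged groups (below). Calls ended for cholesterol without Abiraterone D (adjusted p = 0.095), EMT without Vehicle A (0.185), immediate early without Vehicle C (0.112), histones without Vehicle C, Abiraterone C or D (up to 0.597) and mitochondrial genes without Vehicle C or Abiraterone A (up to 0.911). With the no-gene share as covariate, adjusted p was 0.8 for mitochondrial genes and 0.627 for histones.

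**Figure D2:**
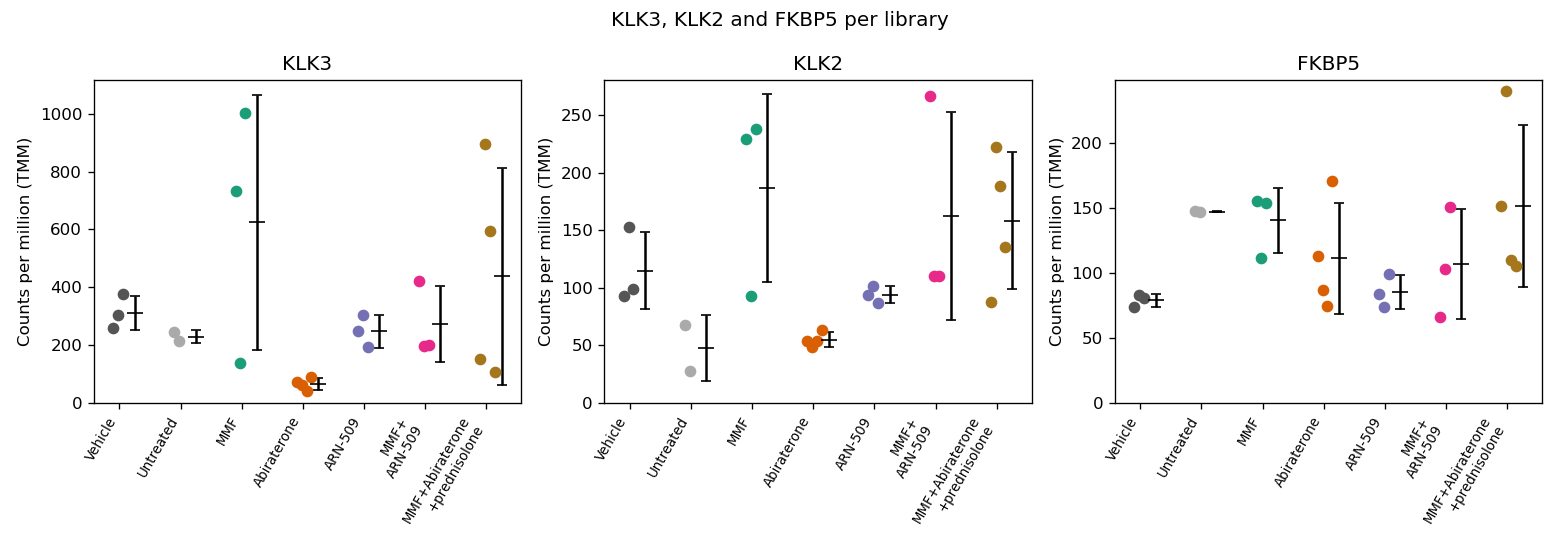
Levels of KLK3, KLK2 and FKBP5 (CPM, TMM scaled, axes from 0) in each of the 22 libraries by group, with group mean ± SD. For KLK3 the 4 abiraterone libraries sit between 40.8 and 88.6 CPM, below all vehicle libraries (259 to 375), and the triple combination libraries run from 107 to 896.

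ARN-509 was compared with vehicle for the effect of the antiandrogen alone. KLK3 was at 248 ± 55.9 CPM against 312 ± 59.0 and KLK2 at 93.9 ± 7.44 against 115 ± 33.3 (log2 fold change -0.29, but 0.09 with untreated and vehicle together as control). Cholesterol synthesis and uptake rose as a list, with 18 of 24 members higher (adjusted p = 0.00386, and adjusted p = 0.849 with an estimated correlation), with SQLE at 10.4 ± 0.862 against 6.25 ± 0.767 CPM and the squalene synthase FDFT1 at 90.5 ± 11.1 against 63.6 ± 9.31. Immediate early and heat shock genes rose as a list, with 24 of 29 members higher (adjusted p = 0.0237, and adjusted p = 0.883 with an estimated correlation). JUN was at 61.0 ± 8.30 against 37.6 ± 2.01. The erythrocyte list fell, with 4 of 4 members lower (adjusted p = 1.35e-08, and adjusted p = 0.281 with an estimated correlation), and all 4 passed adjusted over the list alone; ALAS2 was at 1.40 ± 1.43 against 38.3 ± 39.5. Muscle and fat genes fell as a list, with 11 of 13 members lower (adjusted p = 0.0124, and adjusted p = 0.9 with an estimated correlation). The muscle myosin MYH4 was at 0.0196 ± 0.0339 against 5.51 ± 9.45. Mitochondrial genes rose as a list, with 13 of 13 members higher (adjusted p = 6.91e-06, and adjusted p = 0.883 with an estimated correlation), ribosomal proteins with 38 of 40 higher (adjusted p = 0.00518, and adjusted p = 0.988 with an estimated correlation) and histones with 16 of 17 higher (adjusted p = 0.00518, and adjusted p = 0.902 with an estimated correlation).

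For ARN-509 edgeR called 0 genes, with 579 at an unadjusted p under 0.05, while DESeq2 called 0 and voom 88. ALAS2, HBD, CYP4F8 and RNF17 were among the 5 smallest p-values, none past the threshold (adjusted p = 0.999). CYP4F8, a fatty acid hydroxylase, had no read in ARN-509, which allows up to 0.165 to 0.372 CPM per library, against 4.93 ± 6.77, and RNF17 stood at 0.0792 ± 0.0388 against 11.3 ± 17.8, with 31.8 in Vehicle B. Calls ended for cholesterol without ARN-509 C (adjusted p = 0.0814), immediate early without Vehicle A, Vehicle C or ARN-509 C (up to 0.357), muscle without Vehicle A (0.783), ribosomal proteins without Vehicle B, Vehicle C or ARN-509 A (up to 0.468) and histones without Vehicle C or ARN-509 A (up to 0.344). With the no-gene share as covariate ribosomal proteins turned down (adjusted p = 1.61e-05), and adjusted p was 0.113 for cholesterol, 0.457 for immediate early, 0.0825 for mitochondrial genes and 0.973 for histones.

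MMF with ARN-509 was compared with vehicle as the combination of a nucleotide block with the antiandrogen. Fibroblast and matrix genes fell as a list, with 21 of 22 members lower, median -1.65 (adjusted p = 2.39e-07, and adjusted p = 0.849 with an estimated correlation). The matrix glycoprotein SPARC was at 2.43 ± 2.03 CPM against 9.14 ± 10.2 and the fibrillin FBN1 at 1.95 ± 1.96 against 6.81 ± 7.33. Untreated tumours also had lower fibroblast and erythrocyte lists against vehicle (below). EMT genes fell as a list, with 13 of 15 members lower (adjusted p = 0.00179, and adjusted p = 0.849 with an estimated correlation), endothelium with 9 of 11 lower (adjusted p = 0.0265, and adjusted p = 0.849 with an estimated correlation) and muscle and fat with 12 of 13 lower (adjusted p = 0.0232, and adjusted p = 0.9 with an estimated correlation). The erythrocyte list fell, with 4 of 4 members lower (adjusted p = 1.1e-07, and adjusted p = 0.313 with an estimated correlation). 4 past adjusted over the list alone and HBB was at 15.7 ± 13.7 against 314 ± 289. Fatty acid synthesis rose as a list, with 16 of 18 members higher (adjusted p = 0.00519, and adjusted p = 0.849 with an estimated correlation), with the elongase ELOVL6 at 3.45 ± 1.47 against 0.492 ± 0.396 and the acyl-CoA synthetase ACSL1 at 135 ± 39.4 against 64.7 ± 16.1. Cholesterol synthesis rose as a list, with 17 of 24 members higher (adjusted p = 0.00854, and adjusted p = 0.883 with an estimated correlation). MVD was at 15.4 ± 6.34 against 7.57 ± 1.91. Hypoxia genes rose as a list, with 28 of 35 members higher (adjusted p = 0.00935, and adjusted p = 0.922 with an estimated correlation), with lactate dehydrogenase LDHA at 518 ± 373 against 253 ± 43.9 and ANKRD37 at 9.96 ± 3.45 against 3.67 ± 0.868. Mitochondrial genes rose as a list, with 13 of 13 members higher (adjusted p = 0.00386, and adjusted p = 0.902 with an estimated correlation). KLK3 stood at 273 ± 131 against 312 ± 59.0.

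Here edgeR called 0 genes, with 551 at an unadjusted p under 0.05, while DESeq2 called 3 and voom 1785. The smallest p-values, not past the threshold (adjusted p = 1), were those of HES1, CLDN8, RFX6, RNF17 and ACP5. HES1, a transcriptional repressor downstream of Notch, was at 4.25 ± 1.40 CPM against 11.5 ± 0.286 (log2 fold change -1.41, SE 0.31), and the tight junction gene CLDN8 at 11.7 ± 17.0 against 0.410 ± 0.415. One library ended the calls for cholesterol (Vehicle C or MMF+ARN-509 D, adjusted p up to 0.267), fatty acid synthesis (MMF+ARN-509 D, 0.0662), hypoxia (Vehicle B, MMF+ARN-509 C or D, up to 0.371), EMT (Vehicle B or MMF+ARN-509 D, up to 0.287), endothelium (Vehicle B, MMF+ARN-509 A or D, up to 0.374), muscle (Vehicle A, MMF+ARN-509 C or D, up to 0.733) and mitochondrial genes (Vehicle C or MMF+ARN-509 D, up to 0.651). With the no-gene share as covariate, adjusted p was 0.112 for cholesterol, 0.185 for hypoxia, 0.0602 for EMT, 0.119 for endothelium and 0.964 for mitochondrial genes.

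The triple combination was compared with vehicle. Mitochondrial genes rose as a list, with 13 of 13 members higher, median 1.88 (adjusted p = 8.4e-11, and adjusted p = 0.849 with an estimated correlation), and ribosomal proteins with 40 of 40 higher, median 0.85 (adjusted p = 8.87e-11, and adjusted p = 0.9 with an estimated correlation). RPL28 was at 341 ± 152 CPM against 158 ± 68.8. Markers of other cells fell, the erythrocyte and fibroblast lists as in untreated tumours against vehicle (below). The erythrocyte list fell, with 4 of 4 members lower (adjusted p = 7.55e-07, and adjusted p = 0.387 with an estimated correlation; 4 past adjusted over the list alone), with ALAS2 at 0.458 ± 0.338 against 38.3 ± 39.5. Muscle and fat fell as a list, with 11 of 13 members lower (adjusted p = 0.0101, and adjusted p = 0.9 with an estimated correlation; 8 past adjusted over the list alone), with the muscle calcium pump ATP2A1 at 0.490 ± 0.363 against 4.84 ± 4.59. Fibroblast and matrix fell as a list, with 20 of 22 members lower (adjusted p = 0.0163, and adjusted p = 0.922 with an estimated correlation). The collagen COL12A1 was at 0.739 ± 0.143 against 12.6 ± 11.8. Endothelium fell as a list, with 9 of 11 members lower (adjusted p = 0.034, and adjusted p = 0.864 with an estimated correlation). The VEGF receptor KDR was at 0.327 ± 0.471 against 2.47 ± 2.72. KLK3 was at 438 ± 376 against 312 ± 59.0 (log2 fold change 0.49, but -0.13 without triple combination B and -0.30 with voom), KLK2 at 158 ± 59.4 against 115 ± 33.3, and FKBP5 at 152 ± 62.4 against 79.2 ± 5.00 (adjusted p = 0.514).

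For this comparison edgeR called 0 genes, with 1344 at an unadjusted p under 0.05 (328 higher, 1016 lower), while DESeq2 called 4 and voom 0. ALAS2 and HBD had the smallest adjusted p (0.252), and RNF17 and HBB were also among the smallest p-values (0.514), so none passed. Calls ended for fibroblast and matrix without Vehicle B or triple combination A (adjusted p up to 0.638), endothelium without Vehicle A, Vehicle B or triple combination D (up to 0.247) and muscle without Vehicle A (0.881). With the no-gene share as covariate ribosomal proteins turned down (adjusted p = 3.11e-05) and fibroblast genes had adjusted p = 0.515. The mean log2 fold change of mitochondrial genes went from 2.09 to 0.58 with that covariate, with the call kept.

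MMF with ARN-509 was compared with ARN-509 alone to see what MMF adds. Fibroblast and matrix genes fell as a list, with 20 of 22 members lower, median -1.28 (adjusted p = 6.62e-12, and adjusted p = 0.849 with an estimated correlation), with the membrane metalloprotease MMP14 at 0.206 ± 0.251 CPM against 2.45 ± 1.75 and SPARC at 2.43 ± 2.03 against 10.9 ± 6.94. EMT genes fell as a list, with 12 of 15 members lower (adjusted p = 3.28e-07, and adjusted p = 0.784 with an estimated correlation). The transcription factor ZEB2 was at 3.46 ± 3.04 against 15.7 ± 11.7. Immediate early genes fell as a list, with 23 of 29 members lower (adjusted p = 0.00154, and adjusted p = 0.849 with an estimated correlation). FOS was at 4.09 ± 1.93 against 10.04 ± 1.78. Endothelium fell as a list, with 7 of 11 members lower (adjusted p = 0.0155, and adjusted p = 0.849 with an estimated correlation). Hypoxia rose as a list, with 25 of 35 members higher (adjusted p = 0.0169, and adjusted p = 0.943 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, was at 81.5 ± 55.9 against 48.8 ± 13.8. Ribosomal proteins gave a call downward (adjusted p = 0.008, and adjusted p = 0.989 with an estimated correlation) although their median was 0.07 and 27 of 40 members were higher, so median and test differ in sign. KLK2 was at 162 ± 90.1 against 93.9 ± 7.44 (log2 fold change 0.79, SE 0.44), but 0.22 without MMF+ARN-509 A, 0.23 without the 4 libraries over 25% no-gene reads and 0.31 with voom. By gene edgeR called 0, with 179 at an unadjusted p under 0.05, while DESeq2 and voom each called 0. CLDN8, TIMP3 and BCYRN1, a multicopy RNA of uncertain level, had 3 of the 5 smallest p-values, none past the threshold (adjusted p = 1). One library ended the calls for immediate early genes (MMF+ARN-509 A, adjusted p = 0.865), endothelium (ARN-509 A or C, MMF+ARN-509 A or D, up to 0.394), hypoxia (ARN-509 A, MMF+ARN-509 C or D, up to 0.894) and ribosomal proteins (ARN-509 A or MMF+ARN-509 A, up to 0.911). Without the libraries over 25% no-gene reads ribosomal proteins turned up (adjusted p = 1.09e-09), and adjusted p was 0.811 for immediate early genes and 0.191 for endothelium.

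MMF with ARN-509 was compared with MMF alone to see what ARN-509 adds. KLK3 was at 273 ± 131 CPM against 625 ± 442 (log2 fold change -1.19, SE 0.66), but -0.68 without MMF D, -2.17 without the 4 libraries over 25% no-gene reads and -1.82 with voom. Hypoxia genes rose as a list, with 29 of 35 members higher, median 0.75 (adjusted p = 1.3e-06, and adjusted p = 0.864 with an estimated correlation), with the glycolytic regulator PFKFB3 at 65.0 ± 16.6 against 17.0 ± 7.29 and the histone demethylase KDM3A at 106 ± 22.8 against 41.4 ± 6.53. S phase genes rose as a list, with 36 of 42 members higher (adjusted p = 0.00449, and adjusted p = 0.943 with an estimated correlation) and G2/M genes with 28 of 42 higher (adjusted p = 0.0405, and adjusted p = 0.991 with an estimated correlation). p53 targets fell as a list, with 24 of 32 members lower (adjusted p = 0.0235, and adjusted p = 0.849 with an estimated correlation). MDM2, the ubiquitin ligase of p53, was at 80.9 ± 22.1 against 124 ± 50.5. The unfolded protein response fell as a list, with 17 of 24 members lower (adjusted p = 0.0139, and adjusted p = 0.849 with an estimated correlation). The chaperone HYOU1 was at 57.4 ± 3.18 against 90.0 ± 18.1. Fibroblast genes fell as a list, with 19 of 22 members lower (adjusted p = 0.00252, and adjusted p = 0.9 with an estimated correlation) and ribosomal proteins with 34 of 40 lower (adjusted p = 0.000412, and adjusted p = 0.973 with an estimated correlation).

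For this pair edgeR called 0 genes, with 716 at an unadjusted p under 0.05, while DESeq2 called 2 and voom 158. HES1 had the smallest p, not past the threshold, at 4.25 ± 1.40 CPM against 13.3 ± 2.58 (log2 fold change -1.62, SE 0.31, adjusted p = 0.752), followed by SSPO, RPP25 and BCYRN1. One library ended the calls for hypoxia (MMF C, adjusted p = 0.114), S phase (MMF D or MMF+ARN-509 D, up to 0.931), G2/M (any but MMF C, up to 0.493), p53 targets (MMF B, MMF D or MMF+ARN-509 A, up to 0.358), the unfolded protein response (MMF B or MMF+ARN-509 A, up to 0.147), fibroblast genes (MMF C or MMF+ARN-509 D, up to 0.705) and ribosomal proteins (MMF D or MMF+ARN-509 A, up to 0.268). Adjusted p was 0.968 for ribosomal proteins without the libraries over 25% no-gene reads and 0.105 for G2/M with that share as covariate.

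The triple combination was compared with abiraterone, which differ by MMF and, as far as the labels say, prednisolone. KLK3 was at 438 ± 376 CPM against 66.4 ± 20.2 (log2 fold change 2.72, SE 0.60, adjusted p = 0.317) and KLK2 at 158 ± 59.4 against 55.0 ± 6.35 (1.53, SE 0.38). KLK3 was higher in 4 of 4 triple combination libraries than in any abiraterone library. Fibroblast and matrix genes fell as a list, with 22 of 22 members lower, median -2.29 (adjusted p = 2.89e-09, and adjusted p = 0.849 with an estimated correlation), and 12 passed adjusted over the list alone. COL12A1 was at 0.739 ± 0.143 against 18.0 ± 11.8, COL5A1 at 0.735 ± 0.514 against 5.58 ± 2.94 and FBN1 at 1.94 ± 0.507 against 11.5 ± 6.16. EMT genes fell as a list, with 14 of 15 members lower (adjusted p = 0.000442, and adjusted p = 0.849 with an estimated correlation), 4 of them past adjusted over the list alone (FBN1, PRRX1, SPARC, TAGLN). Of these, FBN1, SPARC and TAGLN are also on the fibroblast list. Endothelium fell as a list, with 9 of 11 members lower (adjusted p = 0.00404, and adjusted p = 0.849 with an estimated correlation). KDR was at 0.327 ± 0.471 against 2.56 ± 1.68. Muscle and fat fell as a list, with 12 of 13 members lower (adjusted p = 0.00307, and adjusted p = 0.883 with an estimated correlation; 2 past adjusted over the list alone), and the erythrocyte list with 4 of 4 lower (adjusted p = 0.000511, and adjusted p = 0.849 with an estimated correlation; 3 past adjusted over the list alone), with HBB at 5.75 ± 5.92 against 101 ± 48.9. Immediate early genes fell as a list, with 22 of 29 members lower (adjusted p = 0.0229, and adjusted p = 0.883 with an estimated correlation), with the matricellular gene CYR61 at 3.56 ± 1.59 against 14.1 ± 6.78, the 1 member past adjusted over the list alone. The unfolded protein response rose as a list, with 16 of 24 members higher (adjusted p = 0.0375, and adjusted p = 0.883 with an estimated correlation). Its transcription factor XBP1 was at 67.4 ± 12.1 against 40.02 ± 5.63. Mitochondrial genes rose as a list, with 13 of 13 members higher (adjusted p = 1.08e-06, and adjusted p = 0.849 with an estimated correlation) and ribosomal proteins with 40 of 40 higher (adjusted p = 2.72e-08, and adjusted p = 0.9 with an estimated correlation).

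Between these groups edgeR called 0 genes, with 2214 at an unadjusted p under 0.05 (1173 higher, 1041 lower), while DESeq2 called 66 and voom 1488, 58 of them shared. The smallest p-values, at adjusted p = 0.317 and not past the threshold, were those of SLC7A6, EBF1, NAA11, CHRM3 and ORM1. The amino acid transporter SLC7A6 was at 30.0 ± 12.4 CPM against 11.2 ± 1.02 (log2 fold change 1.42, SE 0.30), and the transcription factor EBF1 at 0.0976 ± 0.0845 against 4.14 ± 1.89. KLK3 and KLK2 each passed in 4 of 16 alternatives (adjusted p from 4.44e-07 to 0.669 and from 0.0105 to 0.669). The log2 fold change of KLK3 ran from 2.10, without triple combination B, to 3.05, and that of KLK2 from 1.32 to 1.74. Without triple combination C the immediate early call ended (adjusted p = 0.126), without Abiraterone A that of muscle (0.0629), without Abiraterone A, triple combination B or C that of the unfolded protein response (up to 0.234), and with the no-gene share as covariate that of ribosomal proteins (0.536). With that covariate mitochondrial genes kept their call, with a mean log2 fold change of 0.54 in place of 1.49.

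The triple combination was compared with MMF to see what abiraterone and prednisolone add. Nucleotide synthesis rose: de novo purine synthesis with 11 of 14 higher (adjusted p = 0.0222) and pyrimidine and deoxynucleotide synthesis with 16 of 21 higher (adjusted p = 0.0101), each with adjusted p = 0.9 with an estimated correlation. IMPDH2 was at 133 ± 60.9 CPM against 80.8 ± 15.9 and thymidylate synthase TYMS at 25.2 ± 10.7 against 15.3 ± 4.94. Ribosome biogenesis rose as a list, with 30 of 42 members higher (adjusted p = 0.00386, and adjusted p = 0.9 with an estimated correlation), with the nucleolar methyltransferase FBL at 60.5 ± 25.03 against 40.8 ± 5.79, and S phase with 24 of 42 higher (adjusted p = 0.00572, and adjusted p = 0.952 with an estimated correlation). Mitochondrial genes rose as a list, with 13 of 13 members higher (adjusted p = 7.46e-05, and adjusted p = 0.9 with an estimated correlation), ribosomal proteins with 38 of 40 higher (adjusted p = 0.000419, and adjusted p = 0.973 with an estimated correlation), and muscle genes fell as a list, with 11 of 13 members lower (adjusted p = 0.0283, and adjusted p = 0.9 with an estimated correlation). KLK3 was at 438 ± 376 against 625 ± 442 (log2 fold change -0.51, but 0.01 without MMF D). By gene edgeR called 0, with 423 at an unadjusted p under 0.05, while DESeq2 and voom each called 0. JARID2, ZMYND15, GLYATL3, DNAJC1 and RNASEK had the smallest p-values, none past the threshold (adjusted p = 0.999). One library ended the calls for purine synthesis (MMF B, MMF D or triple combination D, adjusted p up to 0.218), pyrimidine synthesis (MMF D or triple combination D, up to 0.136), ribosome biogenesis (MMF D or triple combination B, up to 0.393), S phase (MMF B, MMF D or triple combination D, up to 0.505), muscle (MMF C or triple combination C, up to 0.806) and ribosomal proteins (MMF C or triple combination D, up to 0.836). With the no-gene share as covariate, adjusted p was 0.537 for purine and 0.897 for pyrimidine synthesis, 0.0733 for S phase and, with the direction turned, 0.8 for mitochondrial genes and 3.72e-10 for ribosomal proteins.

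Untreated tumours were compared with vehicle as a pair of controls. MYH14, a nonmuscle myosin heavy chain, fell from 19.7 ± 10.95 to 0.648 ± 0.0392 CPM (log2 fold change -4.92, SE 0.68, adjusted p = 0.00754), and DPP4, a cell-surface dipeptidyl peptidase, fell from 45.6 ± 10.6 to 5.69 ± 0.313 (-3.00, SE 0.44, adjusted p = 0.00841). Both untreated libraries lay below all 3 vehicle libraries for each gene. G2/M genes fell as a list, with 36 of 42 members lower, median -0.94 (adjusted p = 1.39e-06, and adjusted p = 0.9 with an estimated correlation), with topoisomerase TOP2A at 16.8 ± 19.9 against 70.9 ± 48.7, and S phase genes with 31 of 42 lower (adjusted p = 0.0272, and adjusted p = 0.988 with an estimated correlation). Fibroblast genes fell as a list, with 20 of 22 members lower (adjusted p = 0.00366, and adjusted p = 0.902 with an estimated correlation). The collagen COL1A1 was at 13.8 ± 4.20 against 86.4 ± 78.2. The erythrocyte list fell, with 4 of 4 members lower (adjusted p = 0.00366, and adjusted p = 0.849 with an estimated correlation; 4 past adjusted over the list alone). Ribosomal proteins rose as a list, with 39 of 40 members higher (adjusted p = 3.72e-06, and adjusted p = 0.902 with an estimated correlation), with RPS29 at 235 ± 110 against 63.8 ± 47.7, and mitochondrial genes with 13 of 13 higher (adjusted p = 0.0277, and adjusted p = 0.965 with an estimated correlation). Untreated tumours thus moved against vehicle as several drug groups did, with erythrocytes lower and mitochondrial and ribosomal genes higher. Fibroblast genes were lower too, as in both combinations, though not in abiraterone. Their mean log2 fold change was -1.487 in untreated, -1.355 in MMF with ARN-509 and -0.89 in the triple combination. Median log2 CPM of that list was 0.875, 3.09 and 0.949 in Vehicle A, B and C. As in MMF, G2/M and S phase were lower. Median log2 CPM of the erythrocyte list was 3.99, 0.151 and 5.19 in Vehicle A, B and C, and -1.01 and -0.889 in Untreated A and B. Such calls against vehicle cannot be told from a trait of the vehicle libraries. KLK2 was at 47.7 ± 28.5 against 115 ± 33.3 and FKBP5 at 147 ± 0.630 against 79.2 ± 5.00 (adjusted p = 0.205 and 0.23). The log2 fold change of KLK2 (-1.26) was -2.10 without Untreated A and -0.77 without Untreated B.

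These 2 calls, both lower, came with 3340 genes at an unadjusted p under 0.05 (1439 higher, 1901 lower), while DESeq2 called 753 and voom 240. The next smallest p-values, not past the threshold (adjusted p = 0.103), were those of C1orf74, PAQR5 and SYDE2. PAQR5, a membrane progestin receptor, was at 7.36 ± 1.08 CPM against 0.318 ± 0.179. Without Untreated A or Untreated B the adjusted p of MYH14 was 0.165 and 0.0594 and that of DPP4 0.18 and 0.0622, and over 13 alternatives they ran from 1.48e-10 to 0.165 and from 8.65e-09 to 0.18. Calls ended for G2/M without Untreated A (adjusted p = 0.185), S phase without Vehicle A, Vehicle B or Untreated A (up to 0.258), fibroblast genes without Vehicle B (0.0581), ribosomal proteins without Untreated B (0.085) and mitochondrial genes without Vehicle C or Untreated B (up to 0.496), and with the no-gene share as covariate for mitochondrial genes (0.765). The mean log2 fold change of ribosomal proteins went from 0.94 to 0.23 with that covariate, with the call kept.

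Whether MMF acted differently beside another drug was tested by interaction. For MMF with ARN-509, edgeR called 0 genes, with 226 at an unadjusted p under 0.05, while DESeq2 called 0 and voom 1. For MMF with abiraterone, where prednisolone was added as well, edgeR called 0, with 376 at an unadjusted p under 0.05, and DESeq2 and voom each called 0. KLK3 had an interaction of -0.86 (SE 0.93) on the log2 scale beside ARN-509 and 1.72 (SE 0.87) beside abiraterone, neither past the threshold (adjusted p = 1). The former was -0.34 without MMF D and -1.33 without MMF C or MMF+ARN-509 A, and the latter 1.10 without triple combination B and 1.12 with voom. The 5 smallest p-values of the former, none past the threshold, were those of CYP4F8, ALAS2, SSPO, HBD and JARID2, and of the latter those of FMR1NB, ORM1, CYP4F8, JARID2 and SSX1. Beside ARN-509, the MMF effect on hypoxia genes was higher in 32 of 35 members (adjusted p = 0.000512, and adjusted p = 0.9 with an estimated correlation). Beside abiraterone, the effect on fibroblast and matrix genes was lower in 21 of 22 (adjusted p = 1.13e-07, and adjusted p = 0.849 with an estimated correlation) and that on cholesterol synthesis lower in 22 of 24 (adjusted p = 6.56e-05, and adjusted p = 0.849 with an estimated correlation). Leaving out one of 4 libraries (MMF C, ARN-509 A, MMF+ARN-509 C or D) ended the hypoxia call (adjusted p up to 0.295).

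Overlap between treatments was measured on log2 fold changes against vehicle, across genes, which are not independent replicates. Abiraterone and ARN-509 correlated at 0.74, where 5 simulations of unchanged groups on the same controls gave 0.532 on average, and their covariance was 0.556 against 0.337. MMF and the triple combination had a covariance of 0.5 against 0.333, and ARN-509 and MMF with ARN-509 0.463 against 0.334. MMF and abiraterone had 0.203 against 0.333. Genes called for both drugs numbered 0 for each pair, as edgeR called 0 for each drug, and 0 were expected. With untreated in place of vehicle as the control of one drug, so that no control was shared, the covariance was below 0 for each of these pairs: -0.0371 (untreated for ARN-509) and -0.0944 (for abiraterone) for abiraterone and ARN-509, -0.161 (for the triple combination) and -0.68 (for MMF) for MMF and the triple combination, -0.188 (for the combination) and -0.145 (for ARN-509 alone) for ARN-509 and MMF with ARN-509, and -0.457 (for abiraterone) and -0.39 (for MMF) for MMF and abiraterone. Untreated and vehicle libraries differed themselves (3340 genes at an unadjusted p under 0.05). That difference enters each of these values, so they cannot decide whether the drugs overlap. An overlap beyond that of shared controls is not shown.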

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

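Of the tests below, the 2 on the share of reads on no gene were set before their results were seen, and that on host cells and the counts of other splits were chosen only after the result was seen.

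The share of uniquely aligned reads on no gene, which lies outside the gene counts, reached 43.3% in MMF+ARN-509 A, above the highest vehicle library (38.2%). Nuclear-retained RNAs took a larger part of the non-mitochondrial counts where the share was higher (within-group r 0.807, permutation p = 0.00065), so unspliced or nuclear RNA may contribute. Over all libraries their r was 0.781, and 0.754 without the 2 farthest libraries. Genes of silent families, a sign of genomic DNA, also took a larger part (within-group r 0.744, permutation p = 0.00155), but on only 3 to 64 counts per library. For these genes r over all libraries was 0.697, and 0.49 without the 2 farthest libraries. The tests leave both open, and no biological explanation was tested.

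Fibroblast and matrix genes were lower in the triple combination than in abiraterone in 22 of 22 members, and the MMF effect on them differed beside abiraterone (adjusted p = 1.13e-07). If fewer host cells of every type were the cause, endothelial and myeloid genes would be about as low. The endothelial median lay 0.727 above that of the fibroblast list (SE 0.367 over list members), which is under 2 standard errors. This SE is that of a difference of means and takes genes of the same libraries as independent. It leaves out the spread between samples, so the test cannot decide. The 4 measured myeloid members lay 2.16 above (SE 0.35), more than 2 standard errors. At 0.78 and 0.707 CPM on average they are near the floor and were set aside. Most endothelial members share this limit. Their list median was -0.377, -0.404, -2.04 and -2.89 log2 CPM in triple combination A to D. Its group means of 4.43 CPM (abiraterone) and 4.07 CPM (triple combination) include a member that reached 41 CPM. Neither list can therefore decide, and fewer host cells in all stays open as a source. An effect of the drugs on fibroblasts stays open and untested. Whether these reads come from host or tumour cells was not tested either.

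The MMF effect beside ARN-509 differed from that of MMF alone for several lists. Adjusted p was 0.0496 for purine salvage, 0.00163 for cholesterol synthesis, 0.00935 for the unfolded protein response, 0.0272 for NF-kB and inflammatory cytokines and 0.000512 for hypoxia. It was 0.00436 for fibroblast and matrix genes, 3.3e-10 for erythrocytes, 2e-07 for mitochondrial genes and 6.72e-09 for ribosomal proteins. With an estimated correlation the adjusted p was 0.276 for erythrocytes and from 0.849 to 0.902 for the other 8. Both interactions include the vehicle libraries. Against these, untreated tumours also had lower erythrocyte and fibroblast lists and higher mitochondrial and ribosomal lists. Leaving out MMF+ARN-509 A ended the ribosomal call (adjusted p = 0.592). Leaving out 1 library of 7 ended purine salvage (adjusted p up to 0.246: Vehicle A, MMF C, MMF D, ARN-509 B, ARN-509 C, MMF+ARN-509 C or D), of 4 NF-kB (up to 0.26: Vehicle C, MMF C, ARN-509 A or MMF+ARN-509 C), of 3 the unfolded protein response (up to 0.0807: Vehicle A, MMF B or ARN-509 B), of 2 cholesterol (up to 0.093: MMF C or MMF+ARN-509 A) and of 5 fibroblast genes (up to 0.675: Vehicle A, Vehicle C, MMF C, ARN-509 A or MMF+ARN-509 D).

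Beside abiraterone the MMF effect differed for cholesterol synthesis (adjusted p = 6.56e-05), EMT genes (0.00534), fibroblast and matrix genes (1.13e-07), muscle and fat (0.0272) and erythrocytes (0.0354). With an estimated correlation the adjusted p was from 0.849 to 0.9 for these 5. EMT ended without Vehicle A or MMF C (adjusted p up to 0.241). Muscle ended without Vehicle B, Vehicle C, MMF C, Abiraterone A, Abiraterone C, triple combination A or C (up to 0.787), and erythrocytes without Vehicle A, Vehicle C, MMF C, MMF D, Abiraterone D, triple combination A, B or D (up to 0.486).

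One library lay far from the other 3 of its group for 7 of 50 values tested, where 2.5 are expected by chance. In CPM these were CHRM3 (0.0424) and TNS4 (0.0424) in Abiraterone C, IMPDH1 (115) in Abiraterone D, NAA11 (0.0792) in Abiraterone A, HBD (0.0776) in triple combination B, and RNF17 (0.109) and SSX1 (2.28) in triple combination C. For CHRM3, TNS4, NAA11, HBD and RNF17 the other 3 libraries had no read, so these rest on 1 read each.

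Splits of the same libraries into groups of the same sizes were compared by genes at an unadjusted p under 0.05, and each count below includes the real split. Untreated against vehicle, the comparison with genes past the threshold, was not split, so its calls were not checked in this way. For the triple combination against abiraterone 2 of 35 splits gave as many as the real 2214 (highest other 2620), against vehicle 6 of 35 (real 1344, highest 3397), against MMF 30 of 35 (real 423, highest 2900), and for abiraterone against vehicle 5 of 35 (real 837, highest 2753), so chance is not excluded for these 4. Nor is it for the interactions, where 37 of 40 splits gave as many beside ARN-509 (real 226, highest 6504) and 24 of 40 beside abiraterone (real 376, highest 6993). With 10 splits the share cannot fall under 0.05: MMF had as many in 9 (real 309, highest 5659), ARN-509 in 4 (579, 820), MMF with ARN-509 in 5 against vehicle (551, 6745), in 8 against ARN-509 (179, 5362) and in 6 against MMF (716, 5324). Splits that call several times the real count point to a structure of the samples other than their groups. At least as many lists as in the real split were called in 26 of 35 splits for abiraterone against vehicle. For the triple combination this held in 25 of 35 against vehicle, 11 against abiraterone and 10 against MMF. It held in 10 of 40 beside ARN-509 and 31 of 40 beside abiraterone. Of 10 splits it held in 3 for MMF and 6 for ARN-509. For MMF with ARN-509 it held in 8 against vehicle, 6 against ARN-509 and 3 against MMF. Chance is not excluded for these numbers of list calls either.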

How the results depend on the processing

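The covariate for the share of reads on no gene, the omission of 4 libraries with over 25% of it, and all list alternatives except the estimated correlation, fry and the block were chosen only after the data were seen.

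Counts of genes past the threshold are given in the order MMF, abiraterone, ARN-509, MMF with ARN-509 and the triple combination against vehicle, MMF with ARN-509 against ARN-509 and against MMF, the triple combination against abiraterone and against MMF, untreated against vehicle, and the interactions beside ARN-509 and abiraterone. The edgeR counts were 0 except 2 for untreated (unadjusted p under 0.05: 309, 837, 579, 551, 1344, 179, 716, 2214, 423, 3340, 226 and 376). DESeq2 gave 2, 24, 0, 3, 4, 0, 2, 66, 0, 753, 0 and 0. voom with sample quality weights gave 0, 104, 88, 1785, 0, 0, 158, 1488, 0, 240, 1 and 0. The cause was not tested for either. Without a low-count filter edgeR gave 36, 204, 123, 121, 531, 14, 118, 788, 103, 1437, 22 and 89. There the prior degrees of freedom went from 5.53 to infinite, and simulated unchanged groups gave 15 to 36 calls against 0 with the filter.

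With the covariate edgeR gave 1 for MMF with ARN-509 against vehicle and 4 for untreated. Without the 4 libraries it gave 161 for the triple combination against abiraterone. The cause was not tested for either. Without these 4 vehicle keeps 1 library (Vehicle A), so the counts against vehicle and for the interactions say nothing about stability and are left out. With only the groups compared, and so fewer libraries in the model, it gave 5 for the triple combination against abiraterone and 0 for untreated. DESeq2 size factors, the letter as a block and the pooled control kept every count they applied to. Leaving out each library gave 0 to 0, except 0 to 1 for the triple combination against vehicle (1 without Vehicle B) and 2 to 6 for untreated (6 without Untreated B). An untreated group left with 1 library is assumed to vary like the other groups.

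Of the 372 list tests 94 passed. With an estimated correlation 0 passed and with fry 0. With the block 94 passed (80 shared), with the covariate 92 (67 shared, 3 in the opposite direction), without the 4 libraries 101 (59 shared, 4 opposite, with vehicle at 1 library) and with DESeq2 size factors 97 (94 shared). Leaving out each library gave 86 (without MMF B or MMF+ARN-509 D) to 122 (without Vehicle B). Among calls kept without the 4 libraries, the mean log2 fold change of hypoxia genes for MMF with ARN-509 against ARN-509 went from 0.20 to 0.59.

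The covariance of the abiraterone and ARN-509 effects (0.556) became -0.0371 with untreated as the control of ARN-509 and -0.0944 with untreated as the control of abiraterone. The difference between untreated and vehicle libraries enters both of these values, so they cannot decide on an overlap. The fold change of JARID2, MMF+Abiraterone+prednisolone vs MMF, ran from -4.68 (without MMF B) to 0.084 on the log2 scale (without MMF D, the library with its high level), where it reversed. Of the genes named, edgeR without 1 library kept the side of the threshold in 1157 values, with 2 newly past, 4 no longer past and 1 reversed. In every setting here a reversal was counted only if the main unadjusted p was under 0.05 or the alternative passed. Values kept can therefore have changed sign. KLK2 for MMF with ARN-509 against vehicle did so, from 0.50 to -0.085 without MMF+ARN-509 A. DESeq2 kept 134 and put 22 newly past, no filter 107 and 49, voom 128 and 27 (1 no longer past), only the groups compared 134 and 1 (2 no longer past), the covariate 153 and 3, omission of the 4 libraries 149 and 7 (vehicle again at 1 library), and DESeq2 size factors and the block kept 156 each. The median log2 fold change of all genes against vehicle was -0.09 for untreated with TMM and -0.14 with DESeq2 size factors, and closer to 0 in every other comparison under both. Letters did not pair the libraries: same-letter pairs had a median correlation of 0.0248 (-0.721 to 0.611) and 4 of 22 libraries correlated best with their own letter. At this depth the model found 2% to 8% of simulated 2-fold changes.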

Other observations

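Of the 31 lists, 8 passed in no comparison. Their smallest adjusted p was 0.0542 for luminal prostate epithelium (triple combination against abiraterone), 0.0581 for interferon response (ARN-509 against vehicle), 0.0682 for basal epithelium (abiraterone against vehicle) and 0.0863 for glucocorticoid receptor targets (untreated against vehicle). It was 0.0962 for the integrated stress response and 0.156 for myeloid and lymphoid cells (both abiraterone against vehicle), 0.277 for steroid synthesis (MMF with ARN-509 against ARN-509) and 0.334 for neuroendocrine genes (triple combination against MMF).

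Some levels come from single libraries. JARID2 was at 1276 CPM in MMF D, against 18.4 in MMF B and 29.5 in MMF C. The muscle genes CKM and MYH4 were at 9.52 and 16.4 CPM in Vehicle A, against 0 and at most 0.125 in Vehicle B and C. HBB was at 323, 20.9 and 598 CPM in Vehicle A, B and C.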
